A study of Mus musculus with 8 samples.

How the data were processed

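RNA was measured in kidneys of 8 mice, 4 labelled CDH11+/+ and 4 labelled CDH11-/-, all injured with aristolochic acid according to the labels and the design text. The title of the series names another injury (Unx/AngII), and the labels were followed. Per the labels' protocols, frozen tissue was homogenized in Trizol, RNA was purified on a column, and libraries were made with a directional kit that keeps the strand of the transcript. Whether the counting used strand is not given in the sources used here, so reads of overlapping antisense genes may not have been told apart. Mice were grouped by the genotype in their labels. The labels give no replicate number, litter or batch, and replicates were numbered in order of deposit, so a number only names a library.

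The authors deposited a table of counts, whole numbers per Ensembl gene, and a table of normalized values. Per the submitters' processing notes, the build was mm10 and the tools included DRAGEN and DESeq2; their versions, the annotation release and the way reads were assigned to genes are not given in the sources used here. The values of the second deposited table, a signal in units of normalized counts made by the authors, were compared with the counts. Each is the count divided by a factor that differs between genes within a library and has a geometric mean of 1 over the 8 libraries for each gene. Of the factors of 14733 genes with at least 10 counts in every library, taken over genes and libraries, 33.1% lay within 1% of the median of their library. These are therefore not size factors alone. Such factors leave open that the deposited counts are rounded estimates, for instance from transcript quantification; they were analysed as deposited. Both tables were zero for the same genes and libraries. There were 0 columns of other samples.

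Gene names and coordinates came from the GENCODE annotation of GRCm38, the assembly that mm10 names, release M21. Of 42256 identifiers, 42170 had a name there and 86 did not. The unmatched ones held 0.0484% to 0.0580% of a library's counts. Of the 34 named genes past the threshold, 18 overlap another annotated gene, Cdh11 among them (4 gene models on its strand).

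The main test was the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, the edgeR filter on low counts, robust moderation and labelled genotype as the only term. The filter left 15852 genes, and p-values were adjusted by Benjamini-Hochberg over them at a threshold of 0.05. Log2 fold changes were fitted with the default prior count of edgeR, and a prior count of 2 entered log2 CPM values only. A standard error is the absolute log2 fold change divided by the square root of the F statistic. CPM values are scaled by TMM library sizes. The common biological coefficient of variation was 13.5%. Libraries held 10675309 to 18539479 counts, so a gene at 1 CPM rests on few counts and its error is mostly that of counting, while for abundant genes the spread between mice sets the error. Single measures per library were compared by two-sided exact permutation tests, and genes near Cdh11 by a one-sided Fisher's exact test within 10 Mb.

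The 29 gene lists (664 symbols, 662 of them matched to an identifier and 604 tested) cover tubule segments, other kidney cell types, immune cells, matrix, metabolism and stress, and were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives not called later additions. A list with at least 4 tested genes was tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. Camera ranks the list against all other genes; fry asks whether the genes of a list move, on balance, in a common direction. The adrenal list had too few tested genes. Genes of a list were also adjusted over the list alone, with no adjustment across lists. A list score is the mean over its genes of log2 CPM (prior count 2) relative to each gene's mean over the 8 libraries.

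The named genes are Cdh11; in each direction the 12 genes of largest fold change past the threshold whose libraries do not overlap and that reach a mean of 1 CPM in the higher group; the 2 genes of smallest p in each list, 4 for the matrix, tubule injury, proximal tubule and macrophage lists; Havcr1, Lcn2, Col1a1, Col3a1, Fn1, Acta2, Cdh1 and Cdh2; and calls within 10 Mb of Cdh11. Predicted models, pseudogenes and immunoglobulin or T cell receptor segments were counted without being named.

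The alternatives were DESeq2 size factors, library size alone, no filter on low counts, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, edgeR without robust moderation, limma on log2 of the authors' normalized values with a pseudocount of 1, 1 surrogate variable (sva 3.50.0), other thresholds and windows, and leaving out each library in turn. The authors' factors as edgeR offsets, and the estimated correlation without CDH11+/+ replicate 1, were added after the data were seen.

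The steps were tested on simulated data: in 5 simulations of 4 against 4 libraries over 15852 genes with 200 changed, 79.6% of genes changed by a log2 of 1 were recovered and 43% of those changed by 0.5, and 6.42% of calls were false. A list shifted by 0.3 was called in 5 of 5 simulations, and unshifted lists in 1 of 135 tests. Genes were simulated independently of each other. In the real data the estimated correlation was 0.69 in the matrix list, 0.68 in the proximal tubule list and 0.90 in the oxidative phosphorylation list. The simulation therefore does not give the rate of false list calls in these data. Replicates were checked for repeated libraries: between replicates of a genotype, chi-square over its degrees of freedom was 7.19 to 27.0, far above the sampling noise of a repeated library. Counts of Xist and of Y-linked genes were as for males in 8 of 8 libraries. The labels name separate mice, so the spread between replicates is between animals. Figures were drawn with matplotlib 3.10.9.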

Results

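Kidney RNA was sequenced from 8 adult male mice labelled as injured with aristolochic acid, a plant toxin that forms DNA adducts and damages the proximal tubule. The series title names another injury, Unx/AngII, and the labels were followed. The mice, of a mixed 129S1/Sv x C57BL/6 background, had 5 daily doses of 3 mg/kg and were killed 2 weeks after the last dose. Of these, 4 were labelled CDH11+/+ and 4 CDH11-/-. Cadherin-11, encoded by Cdh11, is an adhesion protein of mesenchymal cells. All 8 mice were injured, so no uninjured background could be set beside the values. The libraries labelled CDH11+/+ held 10675309, 13885009, 12885190 and 13181271 counts for replicates 1 to 4, and those labelled CDH11-/- held 14397851, 15632430, 18539479 and 12966177. Totals were 12.7 ± 1.39 M counts (SD, n = 4) against 15.4 ± 2.37 M counts (SD, n = 4), with a two-sided exact permutation p of 0.0857. The smallest p that such a test of 4 against 4 can give is 0.0286. The 10 most abundant genes took 8.53% ± 0.683 of counts in the libraries labelled CDH11+/+ and 8.09% ± 0.602 in the others (SD, n = 4 each, exact permutation p = 0.371). The first principal component, 33.4% of the variance, separated the labelled genotypes without overlap (exact permutation p = 0.0286, 0.229 after Benjamini-Hochberg adjustment over 8 library measures). The second, 22.6% of the variance, placed CDH11+/+ replicate 1 at 41.0 and the other libraries between −26.1 and 9.92.

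Cdh11, the targeted gene, was checked in every library before the genotypes were compared, and its counts were not lower in the libraries labelled CDH11-/-. A transcript that survives the targeting can still be counted, so the counts alone do not show the labels to be wrong. Cdh11 (ENSMUSG00000031673) lies on chromosome 8 from 102632095 to 102785642 of GRCm38, on the minus strand. Its level was 75.6, 58.0, 61.7 and 59.0 CPM (counts scaled to a common library total) in replicates 1 to 4 labelled CDH11+/+. In the libraries labelled CDH11-/- it was 89.9, 91.3, 112.5 and 117.2 CPM, so all 4 lay above every library labelled CDH11+/+. The means were 63.6 ± 8.14 and 102.7 ± 14.1 CPM (SD, n = 4 each), a log2 fold change of 0.69 ± 0.11 (SE, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.0249). In the authors' normalized values, Cdh11 was 1036 ± 235 in the libraries labelled CDH11+/+ and 1222 ± 158 in those labelled CDH11-/- (SD, n = 4 each, two-sided exact permutation p = 0.2). The Cdh11 call ended with limma on those normalized values (log2 fold change 0.26, adjusted p = 0.524) and with the authors' factors entered as edgeR offsets (0.24, adjusted p = 0.531). It also ended, in edgeR, without CDH11+/+ replicate 2 (adjusted p = 0.0836), 3 (0.0631) or 4 (0.108) and without CDH11-/- replicate 3 (0.0683) or 4 (0.0529). Because the targeted gene was not lower in the libraries labelled CDH11-/-, genotypes are given here as labelled. Every direction is that of the libraries labelled CDH11-/- relative to those labelled CDH11+/+.

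**Figure D1:**
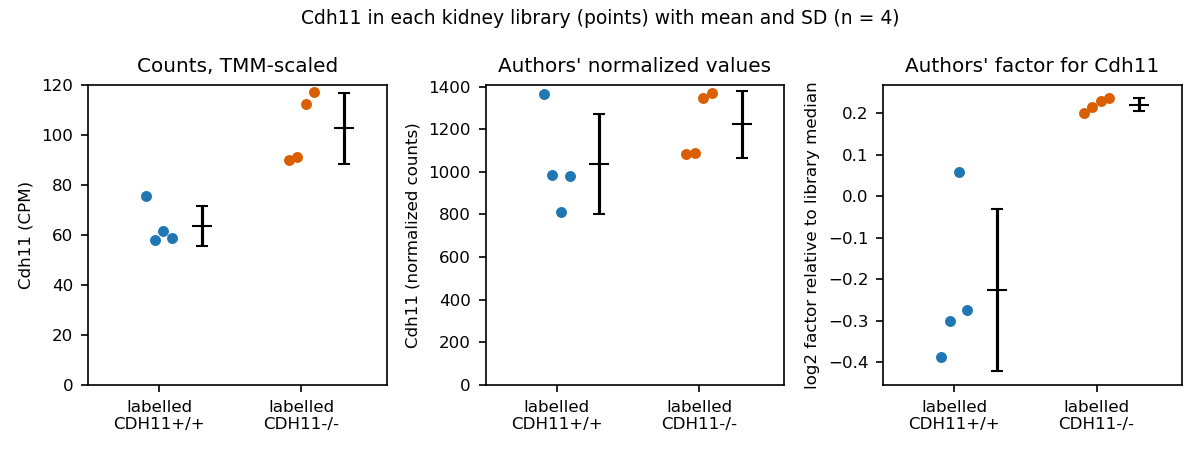
Cdh11 in each of the 8 kidney libraries, by labelled genotype: counts scaled to CPM (left), the authors' normalized values (middle), and the log2 of the authors' factor for Cdh11 relative to the median factor of the library (right). Points are libraries and bars show mean and SD (n = 4), with CPM from 58.0 to 75.6 in libraries labelled CDH11+/+ and from 89.9 to 117.2 in those labelled CDH11-/-.

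The comparison of the labelled genotypes asked which transcripts of the injured kidney differ with cadherin-11. In the libraries labelled CDH11-/-, Adgrg5, Rec8, Zbtb16 and a set of immunoglobulin V segments rose, while Greb1, Gnpda1, Cyp24a1 and Cyp4a14 fell. Complement genes C3, Cfb and C2 fell as well, and markers of injury and fibrosis such as Havcr1, Lcn2 and Col1a1 did not pass the test. Of 15852 genes tested, 57 rose and 58 fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 36 of them by more than 2-fold (21 higher and 15 lower). The 4 libraries of each label did not overlap in any of the 115. Over all tested genes, 7.33% did not overlap, where chance gives 2.86%. Of the 57 that rose, 8 were immunoglobulin V segments, of 58 immunoglobulin or T cell receptor segments tested, and these are counted but not named.

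Among the 12 genes of largest increase, Adgrg5, an adhesion G protein-coupled receptor gene (ENSMUSG00000061577, chromosome 8, 94923694 to 94943280), went from 5.29 ± 1.09 to 24.0 ± 5.20 CPM (SD, n = 4 each). Its log2 fold change was 2.17 ± 0.18 (SE, edgeR quasi-likelihood adjusted p = 0.000433). Rec8, a cohesin subunit of meiosis (ENSMUSG00000002324, chromosome 14, 55618037 to 55625395), went from 3.82 ± 1.76 to 21.8 ± 2.91 CPM (SD, n = 4 each), or 2.53 ± 0.26 on the log2 scale (SE, edgeR adjusted p = 0.00358). Zbtb16, a transcription factor known as PLZF (chromosome 9, 48654297 to 48836222), went from 8.54 ± 4.41 to 47.2 ± 12.2 CPM (SD, n = 4 each), a log2 fold change of 2.45 ± 0.37 (SE, edgeR adjusted p = 0.0403, and 1.34e-06 to 0.153 over 18 alternatives, 7 of which ended the call). Slpi, a secreted inhibitor of leukocyte proteases, rose by 1.66 ± 0.24 and Rgcc, a regulator of the cell cycle, by 1.09 ± 0.15 (log2, SE). The phospholipase gene Pla2g4b rose by 2.28 ± 0.29, the calpain gene Capn3 by 1.39 ± 0.22 and the neuronal gene Stmn2 by 1.58 ± 0.23. The remaining increases were in Tenm2 (1.87 ± 0.30), Slc24a5 (1.86 ± 0.35), Nsun7 (1.25 ± 0.22) and Kcnab1 (1.12 ± 0.18), which were all at a mean of 4.64 CPM or less. Pla2g4b overlaps the gene models Gm28042 and Sptbn5, and Capn3 overlaps Ganc, so their reads could have been shared in the authors' counting.

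Among the 12 genes of largest decrease, Greb1, an estrogen-responsive gene (ENSMUSG00000036523, chromosome 12, 16670615 to 16800886), went from 13.3 ± 5.16 to 0.896 ± 0.433 CPM (SD, n = 4 each). Its log2 fold change was −3.87 ± 0.39 (SE, edgeR quasi-likelihood adjusted p = 0.0034). Gnpda1, a glucosamine-6-phosphate deaminase gene (ENSMUSG00000052102, chromosome 18, 38327535 to 38339003), went from 67.7 ± 13.3 to 17.8 ± 1.79 CPM (SD, n = 4 each), a change of −1.93 ± 0.14 (SE, edgeR adjusted p = 0.000352). With limma on the authors' normalized values this shrank to −1.03 (adjusted p = 0.0153, and 2.90e-33 to 0.0153 over 18 alternatives), and its authors' factor had the largest gap between labels of 14733 genes. The Greb1 call ended in that fit (−2.93, adjusted p = 0.234, the highest over 18 alternatives from 2.39e-22) and with the authors' factors as offsets. Cyp24a1, the vitamin D 24-hydroxylase of the proximal tubule (chromosome 2, 170482708 to 170497145), went from 121.9 ± 25.1 to 30.3 ± 4.57 CPM (SD, n = 4 each), a change of −2.01 ± 0.17 (SE, edgeR adjusted p = 0.00243). The fatty acid omega-hydroxylases Cyp4a14 (−2.51 ± 0.22) and Cyp4a12a (−2.19 ± 0.38) fell too. Both belong to a cluster of close paralogs, so their values are uncertain where the authors' counting could split reads. The succinate receptor gene Sucnr1 (−1.54 ± 0.24), the dicarboxylate transporter gene Slc13a3 (−1.51 ± 0.24) and the transcription factor gene Hnf4g (−1.31 ± 0.26) fell. So did Mmp7 (−1.36 ± 0.23), which encodes matrilysin, Lrmda (−2.82 ± 0.37), Exd1 (−1.31 ± 0.24) and Arhgap36 (−1.15 ± 0.18, log2 and SE throughout). Adjusted p for the 24 genes of largest change ran from 0.000352 to 0.0472 (edgeR quasi-likelihood). Over the 18 alternatives the call of Hnf4g ended in 10, of Exd1 in 9, of Nsun7 and Slc13a3 in 8, and of Tenm2, Kcnab1, Slc24a5 and Sucnr1 in 7. Those of Capn3, Arhgap36, Mmp7 and Cyp4a12a ended in 6, of Pla2g4b in 2, and of Slpi and Stmn2 in 1. Among genes named from the lists, calls ended in 9 (Pcdh17), 8 (Gdf15 and Adgrl4), 7 (Cyyr1) and 5 alternatives (Gpnmb). The count of 115 became 993 without CDH11+/+ replicate 1, 31 without replicate 2 and 27 without replicate 4, and it became 42, 48 and 60 without CDH11-/- replicate 1, 3 and 4. Other fits gave 515 (DESeq2), 679 (limma-voom with quality weights), 514 (1 surrogate variable), 54 (limma on the authors' normalized values) and 65 genes (the authors' factors as offsets).

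**Figure D2:**
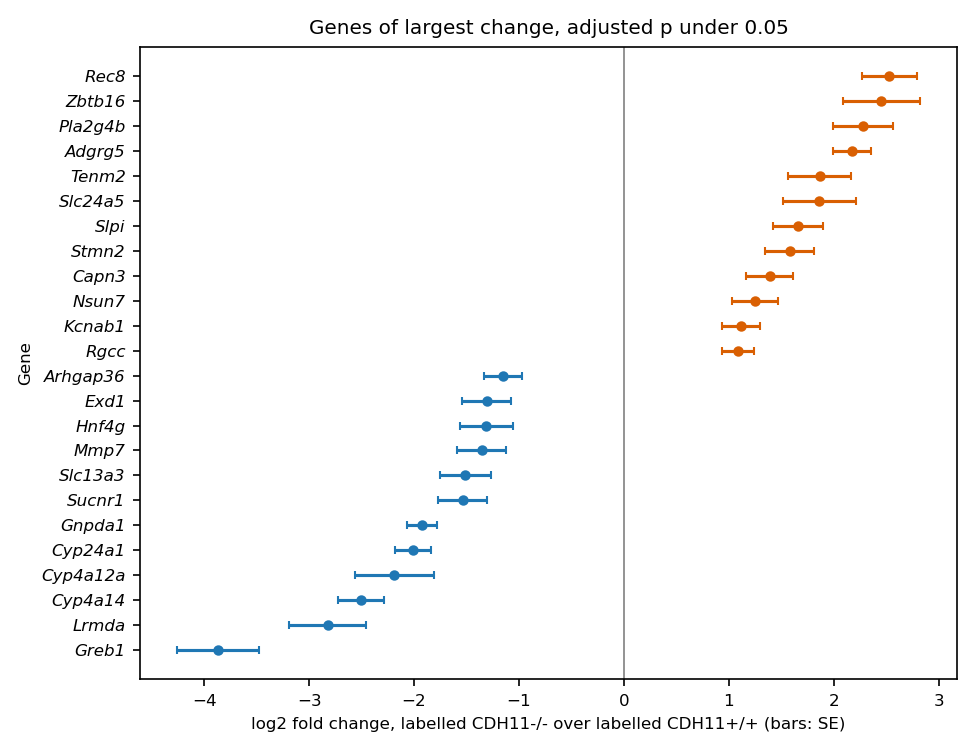
Log2 fold change of the 12 genes of largest increase and the 12 of largest decrease, libraries labelled CDH11-/- over those labelled CDH11+/+ (n = 4 each). Points are edgeR estimates and bars are SE, with values from −3.87 for Greb1 to 2.53 for Rec8.

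Genes of the proximal tubule, the segment that aristolochic acid injures most, were lower as a group in the libraries labelled CDH11-/-. The proximal tubule list had a median log2 fold change of −0.75, and 39 of its 40 measured genes had negative values. Over all genes tested, 1 of the 40, Slc13a3, fell in edgeR, while 16 passed in DESeq2 and 8 in limma-voom, and 18 fell adjusted over the list alone. Other members were the sulfate transporter Slc13a1 (−0.83 ± 0.15, SE, edgeR adjusted p = 0.0544), Cyp4b1 (−1.43 ± 0.25, edgeR adjusted p = 0.0585) and the organic anion transporter Slc22a8 (−2.31 ± 0.40, edgeR adjusted p = 0.0613). With camera at a preset correlation the list passed (adjusted p = 3.08e-14), and it did not at an adjusted p = 0.499 with an estimated correlation. CDH11+/+ replicate 1 had a mean list score of −0.47, within the −0.88 to 0.13 of the libraries labelled CDH11-/-, while the other libraries labelled CDH11+/+ lay between 0.47 and 0.95 (exact permutation p over all 8 libraries = 0.114).

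The fatty acid oxidation list moved the same way, with a median of −0.28 and 27 of 29 measured genes negative. Over all genes tested edgeR called 1 of them, Cyp4a14 (3 in DESeq2 and 5 in limma-voom), and 4 fell adjusted over the list alone, among them Ppara, the nuclear receptor that drives this program (−0.64 ± 0.14, SE, edgeR adjusted p = 0.0742). The other 2, named after their values were seen, were Acsl1 (−0.31) and Acaa2 (−0.42). All 40 oxidative phosphorylation genes had negative values (median −0.18), with Ndufs1, of complex I, at −0.32 ± 0.12 (SE, edgeR adjusted p = 0.25). Of these 40, 0 passed in edgeR, over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05, and 0 passed in DESeq2 or limma-voom. Camera gave adjusted p = 1.55e-07 for the oxidation list (adjusted p = 0.619 with an estimated correlation) and 9.38e-06 for oxidative phosphorylation (adjusted p = 0.705 with an estimated correlation). In the oxidation list CDH11+/+ replicate 1 scored −0.20 where the other libraries of that label scored 0.30 to 0.41, and in oxidative phosphorylation it scored −0.22 where they scored 0.09 to 0.24. With 1 surrogate variable as a covariate, the medians of the proximal tubule, fatty acid oxidation and oxidative phosphorylation lists shrank to −0.46, −0.14 and −0.06. Without CDH11-/- replicate 4 the latter pair gave −0.18 and −0.11, and the oxidative phosphorylation median was −0.11 without CDH11+/+ replicate 3.

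Sterol synthesis and protein folding genes were lower as lists. In the cholesterol synthesis list (median −0.23) 22 of 24 genes were negative. Genes that fell adjusted over the list alone included Acat2 (−0.43 ± 0.09, log2, SE, edgeR adjusted p = 0.0613) and, named after their values were seen, Sqle (−0.37), Stard4 (−0.35) and Msmo1 (−0.36). The list passed with camera (adjusted p = 3.79e-06), but not with an estimated correlation (adjusted p = 0.452). Its mean score did not overlap between the labelled genotypes (exact permutation p = 0.0286, 0.207 after Benjamini-Hochberg adjustment over 29 scores). The heat shock and unfolded protein response list had a median of −0.11 with 19 of 24 genes negative. In edgeR 0 of them passed over all genes (4 at an unadjusted p under 0.05, 2 in DESeq2 and 1 in limma-voom), and adjusted over the list alone 1 fell, the disulfide isomerase Pdia6 (−0.24 ± 0.06, SE, edgeR adjusted p = 0.0847). Its camera adjusted p was 0.00496, with an adjusted p = 0.619 with an estimated correlation. The call also ended without CDH11+/+ replicate 1 (median −0.03, adjusted p = 0.208) and with limma-voom (−0.04, adjusted p = 0.184), and with library size scaling the median was −0.06. Scores of this list overlapped between the labels (exact permutation p = 0.114).

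Genes of the extracellular matrix and of blood vessels were higher as groups. Of 43 measured extracellular matrix and myofibroblast genes, 41 had positive values (median 0.35). In edgeR 0 of them passed over all genes (22 at an unadjusted p under 0.05, 10 in DESeq2 and 14 in limma-voom), and 17 rose adjusted over the list alone. Members included Ccn2, a target of TGF-beta and YAP (0.92 ± 0.18, SE, edgeR adjusted p = 0.0742), Timp2 (0.37 ± 0.08, edgeR adjusted p = 0.0628), Mmp2 (0.53 ± 0.12, edgeR adjusted p = 0.0761) and the fibroblast receptor Pdgfra (0.49 ± 0.11, edgeR adjusted p = 0.0822). Collagen genes Col3a1 (0.48 ± 0.17, SE, edgeR adjusted p = 0.244) and Col1a1 (0.21 ± 0.14, edgeR adjusted p = 0.531), smooth muscle actin Acta2 (0.45 ± 0.22, edgeR adjusted p = 0.408) and fibronectin Fn1 (0.08 ± 0.12, edgeR adjusted p = 0.807) did not pass. The matrix list passed with camera (adjusted p = 3.08e-14) but not at an adjusted p = 0.499 with an estimated correlation. Its score in CDH11+/+ replicate 1 was 0.16, among the −0.06 to 0.35 of the libraries labelled CDH11-/-, and the other libraries labelled CDH11+/+ lay between −0.33 and −0.22.

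All 18 endothelial genes were positive (median 0.29). Cyyr1 (0.70 ± 0.12, SE, edgeR adjusted p = 0.031) and Adgrl4 (0.44 ± 0.08, edgeR adjusted p = 0.0313) rose (8 endothelial genes passed in DESeq2 and 11 in limma-voom), and 10 rose adjusted over the list alone. Endothelial scores did not overlap between the labelled genotypes (exact permutation p = 0.0286, 0.207 after Benjamini-Hochberg adjustment over 29 scores). Camera gave the endothelial list adjusted p = 3.18e-11 (adjusted p = 0.452 with an estimated correlation). Of 14 podocyte genes, 13 were positive (median 0.23). In edgeR 0 of them passed over all genes (6 at an unadjusted p under 0.05, 2 in DESeq2 and 4 in limma-voom). Adjusted over the list alone 5 podocyte genes rose, nephrin, Nphs1 (0.57 ± 0.13, SE, edgeR adjusted p = 0.0759), Synpo (0.29 ± 0.09, edgeR adjusted p = 0.196) and, named after their values were seen, Podxl (0.39), Cdkn1c (0.57) and Wt1 (0.29). The podocyte list had a camera adjusted p = 6.52e-05 (adjusted p = 0.499 with an estimated correlation), and its median was 0.14 without CDH11+/+ replicate 2. Podocyte scores overlapped between the labels (exact permutation p = 0.0857). CDH11+/+ replicates 1 and 3 were at 0.019 and 0.008, above CDH11-/- replicate 2 at 0.005.

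**Figure D3:**
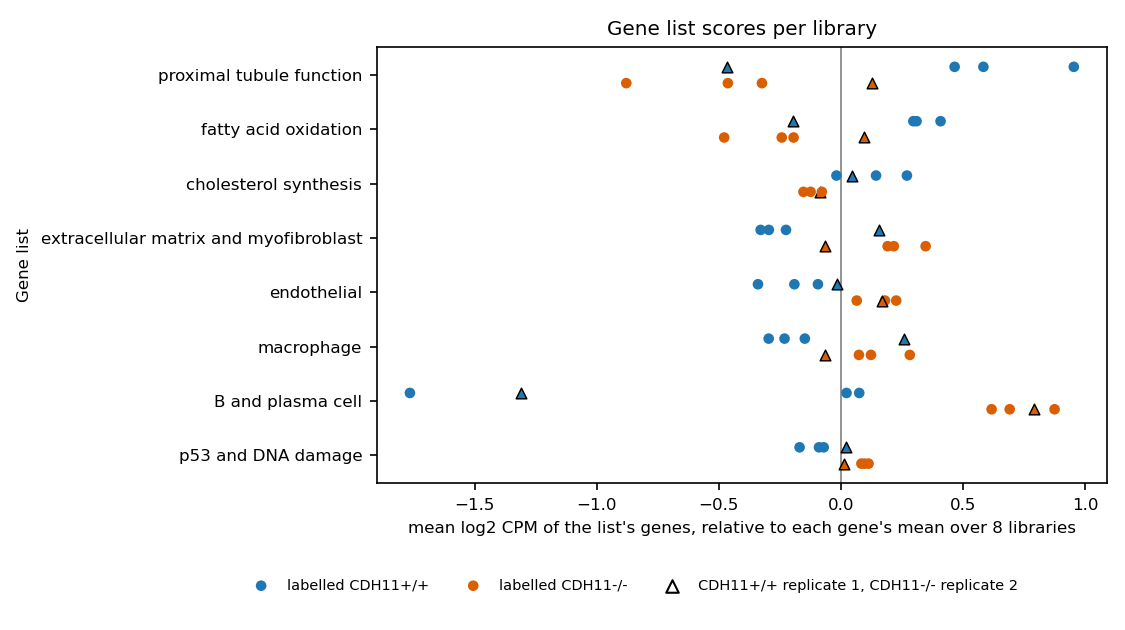
Mean log2 CPM of the genes of 8 lists in each library, relative to each gene's mean over the 8 libraries. Points are libraries by labelled genotype and triangles mark CDH11+/+ replicate 1 and CDH11-/- replicate 2, whose proximal tubule scores were −0.47 and 0.13.

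Macrophage and antibody-producing cell genes were also higher as lists. Of 30 macrophage genes 27 were positive (median 0.14). Gpnmb, a gene of lipid-laden and repair macrophages, rose by 0.58 ± 0.09 (log2, SE, edgeR adjusted p = 0.0246, with 3 macrophage genes past the threshold in DESeq2 and 3 in limma-voom), and 3 rose adjusted over the list alone, with Cd14 (0.96 ± 0.17, SE, edgeR adjusted p = 0.0568) and the chemokine receptor Ccr2 (0.85 ± 0.17, edgeR adjusted p = 0.0704). Camera gave the macrophage list an adjusted p = 0.000103 (adjusted p = 0.705 with an estimated correlation). The macrophage score of CDH11+/+ replicate 1 was 0.26, beside −0.30 to −0.15 in the other libraries of that label and −0.06 to 0.28 in those labelled CDH11-/-. Of 14 B and plasma cell genes 11 were positive (median 0.82). In edgeR 0 of them passed over all genes (5 at an unadjusted p under 0.05, 0 in DESeq2 and 1 in limma-voom), and 2 rose adjusted over the list alone, the secretory pathway genes Derl3 (0.98 ± 0.26, SE, edgeR adjusted p = 0.121) and Mzb1 (1.15 ± 0.34, edgeR adjusted p = 0.166). The list had a camera adjusted p = 2.32e-05 (adjusted p = 0.452 with an estimated correlation). Its scores did not overlap between the labels (exact permutation p = 0.0286, 0.207 after Benjamini-Hochberg adjustment over 29 scores). Libraries labelled CDH11-/- scored from 0.62 to 0.88. Those labelled CDH11+/+ were spread widely, with replicates 1 and 2 at −1.31 and −1.76 and replicates 3 and 4 at 0.08 and 0.02. The macrophage median ranged from 0.08 (without CDH11+/+ replicate 2) to 0.31 (without CDH11+/+ replicate 1), with 0.09 without CDH11+/+ replicate 3 or CDH11-/- replicate 4, and the call ended with 1 surrogate variable (median 0.02, adjusted p = 0.0558). The B and plasma cell median was 0.45, 0.42 and 0.35 without CDH11+/+ replicate 1, 2 or 3, 0.47 without CDH11-/- replicate 4, 0.50 with no filter and 0.53 with DESeq2.

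Among genes of growth arrest and division, 20 of 26 p53 and DNA damage genes were positive (median 0.15). Gdf15, a stress cytokine, rose by 0.51 ± 0.10 (log2, SE, edgeR adjusted p = 0.0388, with 2 genes of the list past the threshold in DESeq2 and 3 in limma-voom). Adjusted over the list alone 7 rose, with Plk2 (0.54 ± 0.14, SE, edgeR adjusted p = 0.114) among them, and 1 fell, Sesn2 (−0.26), named after its value was seen. The p53 list score of CDH11+/+ replicate 1 was 0.020, above the 0.014 of CDH11-/- replicate 2 (exact permutation p over all 8 libraries = 0.0571). Of 31 proliferation genes 28 were positive (median 0.12), with Ube2c at 0.36 ± 0.12 (SE, edgeR adjusted p = 0.218). Of these 31, 0 passed in edgeR, over all genes or adjusted over the list alone, 2 had an unadjusted p under 0.05, and 0 passed in DESeq2 or limma-voom. The proliferation score of CDH11+/+ replicate 1 was 0.09, within the −0.13 to 0.24 of the libraries labelled CDH11-/-. The other libraries of its label lay between −0.17 and −0.09 (exact permutation p over all 8 libraries = 0.286). Camera gave adjusted p = 0.000428 for the p53 list (adjusted p = 0.499 with an estimated correlation) and 0.00142 for the proliferation list (adjusted p = 0.705 with an estimated correlation). The proliferation call ended without CDH11-/- replicate 4 (median 0.08, adjusted p = 0.0729) and with 1 surrogate variable (0.05, adjusted p = 0.0852), and the median was 0.20 without CDH11+/+ replicate 1 or CDH11-/- replicate 2. In all, 12 of 28 lists passed camera with the preset correlation (7 higher and 5 lower). With an estimated correlation 0 passed (1 at an unadjusted p under 0.05, lowest adjusted p = 0.452), and by fry 0 passed (6 unadjusted, lowest adjusted p = 0.138).

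Complement genes moved in both directions. C3, the central component, fell from 2293 ± 185 to 1329 ± 93.8 CPM (SD, n = 4 each), a log2 fold change of −0.79 ± 0.09 (SE, edgeR adjusted p = 0.00263). Factor B, Cfb, fell by 0.86 ± 0.10 (log2, SE, edgeR adjusted p = 0.00358). The neighbouring gene C2, named after its values were seen, fell by 0.36 (log2, edgeR adjusted p = 0.0293). Cfb overlaps the gene models Gm20547 and Mir6972 on its strand, so its reads could have been shared in the authors' counting. The other 14 of the 17 measured complement genes did not pass in edgeR, where DESeq2 called 4 of the 17 and limma-voom 5, and adjusted over the list alone these 3 fell and 1 rose, C3ar1 (0.36), also named after its value was seen. The complement list did not pass (median 0.00, mean −0.07, camera adjusted p = 0.522) and passed on the DESeq2 statistics (adjusted p = 0.0152), with an adjusted p = 0.721 in the main comparison with an estimated correlation.

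Tubule injury markers did not pass as a group (20 genes, median 0.01, mean −0.08, camera adjusted p = 0.309). In edgeR 0 of them passed over all genes (5 at an unadjusted p under 0.05, 2 in DESeq2 and 2 in limma-voom), while Vcam1 (−0.46 ± 0.10, SE, edgeR adjusted p = 0.0759) and Dcdc2a (−0.28 ± 0.08, edgeR adjusted p = 0.132) fell adjusted over the list alone. Kim-1, encoded by Havcr1, was at 0.03 ± 0.13 (SE, edgeR adjusted p = 0.952) and Lcn2 at −0.27 ± 0.24 (edgeR adjusted p = 0.669). The injury list passed with 1 surrogate variable (median −0.07, adjusted p = 0.0237), and had an adjusted p = 0.721 with an estimated correlation and no surrogate variable. Of 22 cadherin and catenin genes 1 fell, the protocadherin gene Pcdh17 (−0.83 ± 0.15, SE, edgeR adjusted p = 0.0335), where DESeq2 called 2 and limma-voom 3, and the list did not pass (median −0.01, camera adjusted p = 0.725). Adjusted over the list alone 1 fell and 2 rose, the desmosomal cadherin Dsg2 (0.36 ± 0.10, SE, edgeR adjusted p = 0.127) and, named after its value was seen, the endothelial cadherin Cdh5 (0.34). E-cadherin, Cdh1, was at −0.06 ± 0.06 (SE, edgeR adjusted p = 0.686) and N-cadherin, Cdh2, at 0.09 ± 0.17 (edgeR adjusted p = 0.858). Ccn1, a matricellular YAP target kept in the immediate early list, rose by 0.91 ± 0.11 (log2, SE, edgeR adjusted p = 0.00536) and was also the 1 gene of that list to rise adjusted over the list alone. The 18 immediate early genes did not pass as a list (median 0.08, camera adjusted p = 0.059). They passed without CDH11+/+ replicate 1 (adjusted p = 0.0271), 2 (0.0313) or 4 (0.0355) and without CDH11-/- replicate 2 (0.00491), and also with DESeq2 (0.0132) and limma-voom (0.0118), all at the preset correlation. With an estimated correlation the adjusted p was 0.705, and 0.629 without CDH11+/+ replicate 1.

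Genes near Cdh11 were compared with the rest because a targeted allele on a mixed background usually carries flanking sequence of the donor strain. Within 10 Mb, 1 of 185 tested genes passed (0.541%), Adgrg5, against 113 of 15659 elsewhere (0.722%, one-sided Fisher's exact test p = 0.739). The other windows tried, 5 and 20 Mb, gave a one-sided Fisher's exact p of 1 and 0.722. Without CDH11+/+ replicate 1, where 993 of all 16065 tested genes passed, the share within 10 Mb was 9.63%, with a one-sided Fisher's exact p of 0.0411.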

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

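The tests on Cdh11, on cell composition, on differences between single mice, on an exchange of libraries and with the authors' factors as offsets were chosen after the result was seen, whereas the splits of the samples and the thinning of counts were not.

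Of 262 groups of 4 libraries examined, 17 had a library far from the other 3 (a gap to the nearest above Dixon's 95% critical value), where chance gives about 1 in 20, or 13.1. CDH11+/+ replicate 1 stood above the other 3 libraries of its label for Timp2 (213.4 CPM), Ccn2 (311.2), Mpeg1 (668.4), Trem1 (2.95) and Col3a1 (628.9 CPM) and for the neutrophil list score (0.15), and below them for the adipose score (−0.26). CDH11-/- replicate 2 stood below the other 3 for Timp2 (215.8 CPM), Ccn1 (168.4) and Zfp36 (56.6 CPM) and above them for Slc24a5 (2.65) and Sucnr1 (1.94 CPM). Among the libraries labelled CDH11-/-, replicate 4 stood above the other 3 for Cp (481.1 CPM) and below them for Adgrl4 (44.5 CPM) and the renin-angiotensin score (−0.36). Tenm2 was highest in CDH11-/- replicate 3 (3.11 CPM) and Kcnab1 in CDH11+/+ replicate 3 (1.98 CPM), each within its own label.

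In the authors' normalized table, which the comparison did not use, the factor for Cdh11 also differed between labels. Relative to the library median, it was −0.23 ± 0.20 in libraries labelled CDH11+/+ and 0.22 ± 0.02 in the others (log2, SD, n = 4 each), a difference of 0.45 (exact permutation p = 0.0286). Cdh11 ranked 18 by the gap between labels and 122 by absolute difference among 14733 genes. The factors of 361 genes (2.45%) did not overlap between labels, where chance gives 2.86%, so the p alone does not set Cdh11 apart.

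Cdh11 was higher in the libraries labelled CDH11-/-. An exchange of 1 library of each genotype is argued against as the cause by all 4 libraries labelled CDH11-/- lying above every library labelled CDH11+/+. An exchange of the labels of both groups stays open, with Cdh11 CPM of the libraries labelled CDH11+/+ at 61.9% of the others, because how much transcript the targeted allele leaves is not known here. Counts not corrected by the authors' factor may account for part of the difference, since with the factors as offsets the log2 fold change went from 0.69 (95% interval 0.42 to 0.97) to 0.24 (−0.12 to 0.61) and the call ended because the fold shrank while the SE went from 0.11 to 0.15. More stromal cells in the libraries labelled CDH11-/- also stay open, as the Cdh11 change was at percentile 95.3 of the extracellular matrix and myofibroblast list, where 2 of 43 genes changed more, and a transcript of altered structure from the targeted allele, the biological explanation, was not tested.

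The proximal tubule list was lower and the matrix list higher in the libraries labelled CDH11-/-, while CDH11+/+ replicate 1 and CDH11-/- replicate 2 lay toward the other label. After thinning every library to 10675309 counts the medians were −0.75 and 0.36, at 99.2% and 104% of their unthinned sizes. Random thinning keeps each gene's expected share of a library, so medians near their unthinned sizes were fixed in advance. The thinning therefore cannot decide on deeper sequencing of the libraries labelled CDH11-/-. Exchanged labels of CDH11+/+ replicate 1 and CDH11-/- replicate 2 stay open, because the values go both ways: Cdh11 (75.6 and 91.3 CPM in the pair, each on its labelled side, and 0.69 as labelled against 0.55 exchanged, edgeR adjusted p 0.0249 and 0.144) and 14 against 6 genes with at least 2-fold between all libraries go with the labels, while 115 against 1471 genes past the threshold go with the exchange. A lower share of proximal tubule cells alone stays open. It would raise the lists of other cell types alike, and the endothelial minus collecting duct score did not separate the labels (exact permutation p = 0.0857). That score holds no proximal tubule genes, so it cannot tell fewer of these cells from a change within them. A difference in injury between single mice, which may be large in this model, remains possible, with an exact permutation p of 0.114 for the proximal tubule score and 0.0571 for the matrix score, and an effect of genotype stays open beside it.

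Chance in the grouping of mice could not be excluded for any of the counts. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least the real 115 genes. The other splits had a median of 0 genes and a highest count of 1471. The split with 1471 is the exchange of CDH11+/+ replicate 1 and CDH11-/- replicate 2 weighed above. It shared 3 genes with the 115, and with a count several times the real one points to a structure of the samples that crosses the labels. For gene lists 16 of the 35 splits gave at least the real 12 (highest other 18, median of the others 11). The 12 lists are thus close to what an arbitrary split gave. For genes within 10 Mb of Cdh11 2 of the 35 gave at least the real 1 (highest other 14, median of the others 0). These are the same 2 splits as for all genes. A split that called no gene could have none near Cdh11, so this count is not a separate test of the region.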

How the results depend on the processing

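The authors' factors as offsets, and the estimated correlation without CDH11+/+ replicate 1, were chosen after the data were seen. No paired analysis was possible because the labels give no replicate numbers shared between the groups, the numbers used here following the order of deposit. The count of 115 genes (57 higher, 58 lower) was 120 to 148 with DESeq2 size factors, library size alone, no filter, a 1 CPM filter or no robust moderation. It became 515 (242 higher, 273 lower) with DESeq2, 679 (337, 342) with limma-voom, 514 (248, 266) with 1 surrogate variable, 54 (27, 27) with limma on the authors' normalized values, 65 (32, 33) with the authors' factors, 312 (150, 162) at an adjusted p under 0.1 and 36 (21, 15) with an added absolute log2 fold change above 1. DESeq2 called all 115 among its genes, and the authors' factors kept 57 of them. Leaving out each library in turn gave 27 to 993 genes, 13 to 492 higher and 13 to 501 lower, the highest without CDH11+/+ replicate 1 (114 of the 115 kept) and the lowest without CDH11+/+ replicate 4 (26 kept), with 31 without CDH11+/+ replicate 2 and 42, 48 and 60 without CDH11-/- replicates 1, 3 and 4. Cdh11 went from 0.69 to 0.26 with the authors' normalized values and 0.24 with their factors, and over left-out libraries from 0.64 to 0.80 (edgeR adjusted p 0.00282 to 0.108, not past the threshold without CDH11+/+ replicates 2, 3 or 4 or CDH11-/- replicates 3 or 4). Of 33 other named genes past the threshold, 11 stayed past it in all 18 settings, among them Adgrg5, Rec8, Rgcc and Ccn1 higher and Gnpda1, Cyp4a14, Cyp24a1, Lrmda, C3 and Cfb lower, with Gnpda1 between −2.04 and −1.03. Of the 34 with Cdh11, leaving out a library kept 14 to 34. Of the 12 gene lists, 0 passed with an estimated correlation (0 higher, 0 lower), 0 by fry (0, 0) and 0 with an estimated correlation without CDH11+/+ replicate 1 (0, 0), while left-out libraries gave 12 to 15 lists (6 to 10 higher, 5 to 6 lower). The heat shock list was lost with limma-voom and without CDH11+/+ replicate 1, the macrophage list with 1 surrogate variable, and proliferation with 1 surrogate variable and without CDH11-/- replicate 4. The share of genes within 10 Mb of Cdh11 past the threshold was 0.529% to 9.63% over left-out libraries, the highest without CDH11+/+ replicate 1, where 993 of all 16065 genes passed (one-sided Fisher's exact p = 0.0411). With DESeq2, limma-voom and 1 surrogate variable, which called more genes in all, this share was 3.92%, 4.86% and 5.41%. The one-sided Fisher's exact p was 0.209, 0.395 and 0.0786. The differences in library measures, a value with no test at 3 against 4, ran from 1.68 to 3.53 M counts, −0.70 to −0.15 percentage points of the 10 most abundant genes and 33.5 to 45.8 on the first principal component. No result past the threshold changed sign, and sign changes of values past it in neither fit were not counted. List tests were not repeated without robust moderation, which does not enter camera. The adjusted p of 0.1 and the fold limit change counts by construction, and otherwise the cause was not tested. Thinned to 10675309 counts each, the libraries gave 121 genes, 102 of them among the 115, and at the real depths a log2 change of 0.5 was recovered for 43.0% of simulated genes.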

Other observations

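The test on neighbouring genes past the threshold was chosen after the result was seen, whereas the list of other glucocorticoid targets was written before their values were seen.

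In the T and NK cell, neutrophil, cytokine and Wnt lists, which did not pass camera, single genes passed in edgeR only when adjusted over their list alone. Granzyme genes Gzma (−1.38 ± 0.34, SE, edgeR quasi-likelihood adjusted p = 0.0954) and Gzmb (−0.94 ± 0.25, edgeR adjusted p = 0.125) fell adjusted over the list alone in the libraries labelled CDH11-/-, although the median of the 27 T and NK cell genes was 0.16 (camera adjusted p = 0.0629). Gzma overlapped between the labels, with CDH11+/+ replicate 4 at 2.70 and CDH11-/- replicate 4 at 2.73 CPM. Of 7 neutrophil genes (median 0.12, camera adjusted p = 0.339) Mmp9 rose adjusted over the list alone (0.98 ± 0.23, SE, edgeR adjusted p = 0.0847). Of 31 cytokine and NF-kB response genes (median −0.06, camera adjusted p = 0.602) Tnfaip2 rose (0.36 ± 0.08, SE, edgeR adjusted p = 0.0618) while Icam1 (−0.26 ± 0.06, edgeR adjusted p = 0.08) and, named after its value was seen, Cxcl1 (−0.64) fell, adjusted over the list alone. Of 22 Wnt and beta-catenin targets (median 0.12, camera adjusted p = 0.0665) the feedback inhibitor Nkd1 (0.75 ± 0.16, SE, edgeR adjusted p = 0.0645) and Dkk3 (0.37 ± 0.09, edgeR adjusted p = 0.0871) rose adjusted over the list alone. The Wnt score was 1 of 4 list scores without overlap between the labelled genotypes (exact permutation p = 0.0286, 0.207 after adjustment over 29 scores).

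In the remaining lists no gene passed adjusted over the list alone. These were the interferon response (30 genes, median −0.07, camera adjusted p = 0.058), thick ascending limb and distal convoluted tubule (18 genes, −0.13, 0.13), collecting duct (18 genes, −0.02, 0.942), renin-angiotensin (9 genes, −0.05, 0.479), circadian clock (17 genes, 0.12, 0.309), adipose (5 genes, −0.02, 0.905), urothelium (9 genes, 0.45, 0.15) and red blood cell lists (4 genes, 0.20, 0.178). The adrenal list had Star alone (0.17 ± 0.22, SE, edgeR adjusted p = 0.77). Over all genes tested, 0 genes of these lists, or of the T and NK cell, neutrophil, cytokine and Wnt lists, passed in edgeR. DESeq2 and limma-voom each called 2 T and NK cell, 1 neutrophil and 2 Wnt genes, called 4 and 3 cytokine genes, and called 0 genes of the other lists named here. At an unadjusted p under 0.05 edgeR had 6 T and NK cell, 1 neutrophil, 9 cytokine, 2 Wnt, 2 interferon, 2 ascending limb, 2 collecting duct, 2 renin-angiotensin, 3 clock, 1 adipose, 3 urothelium and 0 red blood cell genes. Camera calls at the preset correlation appeared when libraries were left out, for the ascending limb list without CDH11+/+ replicate 1 (median −0.20, adjusted p = 0.000245) or CDH11-/- replicate 2 (0.0407) and the urothelium list without CDH11+/+ replicate 1 (0.0296). With an estimated correlation these lists did not pass without CDH11+/+ replicate 1 (0.495 and 0.509), and that correlation was not run without the other libraries. In the fit of all 8 libraries it gave the lists of this paragraph and the Wnt, neutrophil and T and NK cell lists 0.452 or more. Preset-correlation calls also appeared for T and NK cells without CDH11+/+ replicate 3 (0.0116) or 4 (0.014) or CDH11-/- replicate 2 (0.0387) or 3 (0.00481), and for interferon genes without CDH11+/+ replicate 2 (0.0332) or 4 (0.0147) or CDH11-/- replicate 1 (0.00377) or 4 (0.000955). The red blood cell list passed without CDH11+/+ replicate 2 (0.0313), and the neutrophil and Wnt lists without CDH11-/- replicate 3 (0.0438 each). Other tools also added calls, DESeq2 for the Wnt list (0.0252), limma-voom for the interferon and ascending limb lists (0.0118 each) and 1 surrogate variable for the interferon (0.0169), clock (0.0496) and red blood cell lists (0.0372).

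Fkbp5, a classical glucocorticoid target singled out after its values were seen, rose with Zbtb16 in the libraries labelled CDH11-/- (126.1 ± 30.3 against 237.3 ± 24.0 CPM, SD, n = 4 each, log2 fold change 0.91, edgeR adjusted p = 0.0403). A higher glucocorticoid response would be a candidate explanation. In a list of 18 other targets written before their values were seen, the median log2 fold change was −0.0398 (SD 0.65, range −0.65 to 2.49), with 8 positive and 10 negative, and 29 of the 35 splits of the libraries gave a mean score difference as large. These 18 targets thus showed no common rise. Fkbp5 was singled out by its value, so its distance from their median cannot decide the cause. A general glucocorticoid response is not excluded in 4 against 4 mice.

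The mixed background could make strain segments shared within a labelled genotype appear as clusters of called genes. Of 106 called genes, 24.5% had another call within 2 Mb once pairs of the same gene family were left out, against a mean of 24.0% in 10000 random draws of tested genes (one-sided permutation p = 0.493). No excess was detectable, and single segments stay open. Neighbouring calls moved in both directions on chromosome 2, with Exd1 (−1.31) at 119516505, Pla2g4b (2.28) at 120033417 and Capn3 (1.39) at 120456019.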
